A study of Mus musculus with 6 samples.

How the data were processed

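RNA was profiled in total hematopoietic cells, sorted for the surface antigen CD45 (the product of Ptprc, carried by nearly all leukocytes), from the spleen and the mesenteric lymph node (mLN) of wild-type C57BL6/J mice. Per the labels, the cells were freshly prepared, RNA was extracted with a phenol-based reagent and cleaned on columns, and polyA libraries were made with a directional (strand-keeping) kit. There were 3 spleen and 3 mLN libraries, grouped by the tissue in their labels.

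The authors deposited a gene table of the kind the program RSEM writes for each library. The submitters' processing notes name STAR, RSEM and the mouse build mm10. Versions, parameters, the transcript annotation and the strand setting of the counting are not given in the sources used here. The authors' tables hold an expected count for each gene, an estimate that splits reads shared by several transcripts and need not be whole. Per the file headers they also hold an effective length and a TPM value, a transcript abundance scaled to the same total in each library. The expected count was tested, the effective length entered 1 alternative, and TPM was used only to check that each library summed to 1000000. Each table held 55487 Ensembl gene identifiers. Of these, 55141 matched a symbol in GENCODE M21 (build GRCm38, the assembly also called mm10), and the other 346 held 0.0356% to 0.0446% of the counts of a library. Coordinates come from that annotation, are 1-based and give the extent of the whole gene.

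Genes with close copies share reads that RSEM apportions by a model, so values of single members are uncertain. These include Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ifit3 and Ifit3b, Hspa1a and Hspa1b, Ly6c1 and Ly6c2, Trbc1 and Trbc2, the Apol and Cd209 families, and immunoglobulin and T-cell receptor segments. Overlapping and antisense genes are uncertain likewise, since the strand setting is not known.

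Expected counts were rounded to whole numbers. Genes were kept with filterByExpr by group, which left 14427, and libraries were scaled with TMM factors. The test was the quasi-likelihood F-test of edgeR 4.0.16 (robust, tissue as the only term) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Calls with an absolute log2 fold change of at least 1 were counted beside them. Fold changes are mLN over spleen. Levels are TMM-scaled CPM (the count scaled to a library of 1000000 counts), given as mean ± SD with n = 3 in each tissue. Standard errors (SE) of log2 fold changes were taken from the F statistic. Adjusted p-values of single genes are from this edgeR test.

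Fixed lists of marker genes (30 cell types) and of functions (18) were compared with all other tested genes by camera in limma 3.58.1. It used its preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, adjusted over the 46 lists with at least 3 tested members. Camera with an estimated correlation was run beside it. Its adjusted p was higher also for lists with estimates below the preset, so a call lost there does not by itself show correlation between genes. Fry, which tests each list by itself, was run as well and called 39 lists in its directional and 45 in its mixed form. For the balance of the main lymphocyte classes, the mean log2 CPM of the pan-B list was subtracted from that of the pan-T list in each library. Tissues were then compared by an exact two-sided permutation test over all 20 assignments, whose smallest possible p is 0.1.

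Genes were named by a rule. It takes called genes whose tissues do not overlap in CPM and whose mean is at least 10 CPM in the higher tissue, and of these the 12 largest rises and the 12 largest falls by fitted log2 fold change. Immunoglobulin and T-cell receptor segments, predicted genes, pseudogenes and mitochondrial genes are left out there. From each list it takes up to 2 called members with the largest rise and 2 with the largest fall or, where none was called, the 2 with the highest mean. Named whatever their values were Ptprc, Cd3e, Cd4, Cd8a, Foxp3, Ncr1, Itgax, Adgre1, Csf1r, S100a8, Hbb-bs, Spic, Ccr7, Ccr9, Igha, Xist and Ddx3y. Some genes the rule takes are not reported here. Groups, the tests described above, lists, this rule and all alternatives but the assumed coefficients of variation were chosen before the data were examined, while other tests among the additional observations were not.

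Where a gene had no counts in a tissue, its fold is a lower bound set against a floor of 3 counts over that tissue's libraries. Where it had 1 to 3 counts, the ratio is given with an exact 95% interval. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

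Libraries held 12584244 to 18119551 expected counts. The test was tried on simulated counts for the 14427 genes of this comparison, with 200 genes changed. It recovered 21 of 50 genes changed 1.25-fold, 33 of 50 changed 1.5-fold, 40 of 50 changed 2-fold and 48 of 50 changed 4-fold. It also called 12 unchanged genes, 7.79% of all calls. Of simulated lists, camera in limma called all 10 raised 1.5-fold and 0 of 40 unchanged. Simulated genes were drawn independently, so these lists held no correlation between genes, while estimates for real lists reached 0.303 (follicular B cell). The trial therefore does not show how camera behaves with such correlation. In the data 6569 genes were called, far more than the 200 changed here, so the shares recovered and called wrongly need not hold for the data.

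Alternatives were size factors of the DESeq2 type, library totals alone, no filter or a stricter one, and leaving out immunoglobulin, T-cell receptor, haemoglobin, mitochondrial and ribosomal protein genes. Others were leaving out each library, the replicate number as a block, an offset for effective length, DESeq2 1.42.0, limma-voom, a fit without robust dispersion, an adjusted p under 0.01, a prior count of 0.5 and the other list tests. Coefficients of variation of 0.2 and 0.4, assumed for every gene in a likelihood ratio test of edgeR, were added after seeing the data.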

Results

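To compare gene expression between hematopoietic cells of the spleen and of the mesenteric lymph node (mLN, the node that drains the intestine), polyA RNA of sorted CD45+ cells was measured in 3 libraries of each tissue. The spleen libraries held 17133045, 16163783 and 16450080 expected counts and the mLN libraries 15252157, 18119551 and 12584244. Across genes, which are not independent replicates, log2 CPM correlated with Pearson coefficients from 0.984 to 0.989 within a tissue and from 0.934 to 0.937 between tissues. Within a tissue, each pair of libraries differed by more than sampling noise (median squared difference 2.48 to 2.96 times that of counting alone), and all 6 were kept as separate samples. This excess does not show that they are biological replicates. The common coefficient of variation that edgeR estimated between libraries of a tissue was 0.055. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Ptprc, which encodes CD45 itself (chromosome 1, 138062861 to 138175708, GRCm38), stood at 2191 ± 39 CPM in spleen and 2675 ± 35 CPM in mLN (SD, n = 3 each), a log2 fold change of 0.29 (adjusted p = 3.64e-15).

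T-cell genes were higher, and B-cell, erythroid and granulocyte genes lower, in mLN than in spleen. The largest rise among named genes of at least 10 CPM was that of Marco, a scavenger receptor of macrophages (chromosome 1, 120474538 to 120505024). It stood at 0.355 ± 0.153 CPM in spleen and 20.4 ± 1.38 CPM in mLN (log2 fold change 5.81, SE 0.235, adjusted p = 9.43e-24). Next came Siglec1, another macrophage receptor (3.40 on the log2 scale), the actin-bundling gene Fscn1 (3.28), Apol7c (from 6.88 ± 0.593 to 55.1 ± 1.46 CPM), the chemokine gene Ccl22 (2.98) and Igfbp4 (2.97). The other large rises were Pdlim4 (2.96), Igsf23 (2.86), Cacnb3 (2.84), Ly6c1 (2.70), Spsb1 (2.59) and Tspan9 (2.47). The 12 largest falls by fitted value were all in genes with 0 to 3 counts in the mLN libraries together. Fitted values of such genes depend on the prior count, and genes outside the 12 had measured ratios above some of the bounds given here. Car1, a carbonic anhydrase of red cells (chromosome 3, 14766216 to 14808368), was at 72.6 ± 1.95 CPM in spleen and had no counts in mLN, at least 1091-fold lower. With no mLN counts either, the granule protease gene Elane was at least 466.3-fold lower and Add2 at least 456.2-fold. Rhag was at least 336.3-fold lower, Btnl10 at least 322.6-fold, Kel at least 277.6-fold and Cldn13 at least 266.3-fold. The red-cell anion exchanger gene Slc4a1 was at 256 ± 2.60 CPM in spleen with 2 counts in mLN, a ratio of 5774 (95% interval 1598 to 47680). The granule gene Ltf had 3 mLN counts, a ratio of 4978 (1703 to 24140), and Camp had 1, a ratio of 3545 (635.9 to 140100).

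Of 14427 genes tested, 6569 differed between the tissues by edgeR's quasi-likelihood test, 3139 higher and 3430 lower in mLN. Changes of at least 2-fold were made by 529 of the higher and 1241 of the lower genes. With an assumed coefficient of variation of 0.2 for every gene, 2868 genes were called, and with 0.4, 923. Of 46 gene lists tested, 31 were called by camera in limma, 11 higher and 20 lower. With an estimated correlation 14 calls held: pan-T, naive T cell, migratory dendritic cell, interferon and immediate-early upward, and pan-B, neutrophil, monocyte, basophil, erythroid, progenitor, cell cycle, class II and haem synthesis downward. Counts of list members below are over all genes tested. Adjusted over the list alone they were the same except in 6 of the tested lists, where the second count is given.

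**Figure D1:**
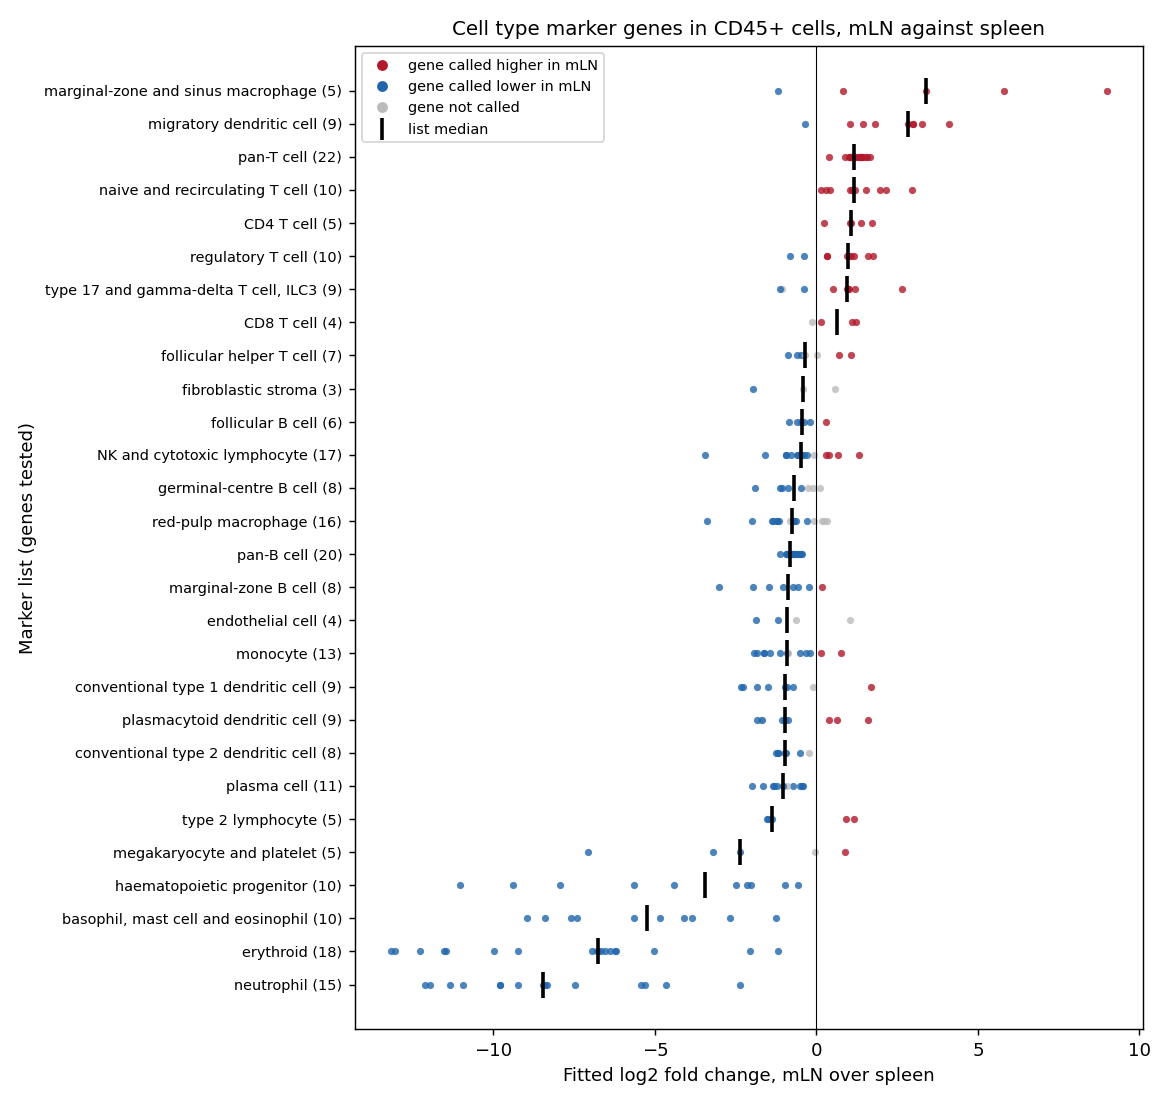
Fitted log2 fold change (mLN over spleen, horizontal axis) of each tested member of the cell type marker lists (vertical axis, number of genes tested in brackets), colored by call, with a bar at the list median. All 15 neutrophil and all 18 erythroid genes lie below 0 and all 22 pan-T genes above it, and fitted values of genes with no counts in a tissue depend on the prior count and are not bounds.

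All 22 tested genes of the pan-T list rose in mLN, with a median log2 fold change of 1.17 (camera adjusted p = 8.81e-18). Cd3e, a chain of the T-cell receptor complex (chromosome 9, 44998740 to 45009627), rose from 132 ± 3.71 to 269 ± 5.10 CPM (log2 fold change 1.03, SE 0.0354, adjusted p = 3.45e-26). Trat1 rose by 1.57 on the log2 scale. All 10 genes of the naive and recirculating T-cell list rose (median 1.16, adjusted p = 3.46e-08), among them Igfbp4, from 95.0 ± 3.01 to 743 ± 4.92 CPM, and Dapl1 (2.17). Ccr7, a lymph node homing receptor gene, rose by 1.03. All 5 genes of the CD4 list rose (median 1.08, adjusted p = 0.00043, but adjusted p = 0.0553 with an estimated correlation). Cd4 rose from 115 ± 3.64 to 301 ± 12.3 CPM and Cd40lg by 1.72. In the CD8 list 3 of 4 genes rose (median 0.62, adjusted p = 0.0261, but adjusted p = 0.118 with an estimated correlation), with Cd8a at 229 ± 10.7 CPM in spleen and 489 ± 14.7 CPM in mLN. In the regulatory T-cell list 8 of 10 genes rose and 2 fell (median 0.97, adjusted p = 0.004, but adjusted p = 0.107 with an estimated correlation). Foxp3, the transcription factor gene of these cells, rose from 14.3 ± 1.81 to 28.7 ± 1.45 CPM, while Tigit and Ikzf2 had log2 fold changes of -0.82 and -0.38. The follicular helper list was not called by camera (2 higher and 3 lower of 7, adjusted p = 0.635), with Icos at 1.08 and Pdcd1 at -0.89. Nor was the list of type 17 and gamma-delta T cells and ILC3 (6 higher and 2 lower of 9, adjusted p = 0.239), with Tmem176a at 1.21 and Ccr6 at -0.39. The type 2 lymphocyte list was not called by camera (2 higher and 3 lower of 5, adjusted p = 0.635), with Gata3 at 0.92 and Il1rl1 at -1.51.

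All 20 tested genes of the pan-B list fell in mLN (median log2 fold change -0.81, camera adjusted p = 2.03e-12). Blk, a kinase gene of B cells (chromosome 14, 63372836 to 63417037), fell from 267 ± 2.54 to 123 ± 2.76 CPM (log2 fold change -1.12, SE 0.0354, adjusted p = 2.11e-27). Fcrla had a log2 fold change of -0.94. The pan-T to pan-B log2 ratio was -2.02 ± 0.0159 in spleen and -0.0584 ± 0.0247 in mLN (SD, n = 3 each). The difference was 1.96, with all 3 mLN libraries above all 3 spleen libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). This is a balance of RNA, not of cell numbers. The marginal-zone B-cell list fell (7 lower and 1 higher of 8, median -0.88, adjusted p = 0.00146, but adjusted p = 0.107 with an estimated correlation), with S1pr3 at -3.03, Fcrl5 at -1.97 and Dtx1 at 0.18. The follicular B-cell list fell (5 lower and 1 higher of 6, median -0.44, adjusted p = 0.0207, but adjusted p = 0.268 with an estimated correlation). Its call was also lost (adjusted p = 0.0605) when immunoglobulin, T-cell receptor, haemoglobin, mitochondrial and ribosomal protein genes were left out. In the germinal-centre list 5 of 8 genes fell, or 6 adjusted over the list alone (median -0.68, adjusted p = 0.018, but adjusted p = 0.107 with an estimated correlation). They included Gcsam, with a log2 fold change of -1.90. In the plasma-cell list 10 of 11 genes fell (median -1.03, adjusted p = 2.14e-06, but adjusted p = 0.0732 with an estimated correlation). Jchain, which joins polymeric antibodies, fell from 633 ± 6.91 to 159 ± 2.24 CPM. All 10 class II presentation genes fell (median -0.59, adjusted p = 2.20e-06), with H2-Eb1 at -0.64 and H2-DMb2 at -0.63.

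Among immunoglobulin constant genes 8 fell and 3 rose of 12 (median -0.88, adjusted p = 0.0103, but adjusted p = 0.126 with an estimated correlation). Ighm fell from 8440 ± 165 to 1987 ± 34.7 CPM, and Ighg2c had a log2 fold change of -2.24. Igha, the heavy chain gene of IgA (chromosome 12, 113254830 to 113260236), rose from 146 ± 4.87 to 393 ± 10.4 CPM (log2 fold change 1.43, SE 0.0338, adjusted p = 7.29e-32). Ighe rose by 1.90 to 15.3 ± 1.12 CPM. Of the variable segments tested, 61 of 73 Ighv and 75 of 84 Igkv genes fell, while 34 of 48 Trav and 19 of 19 Trbv genes rose. Immunoglobulin genes took 1.56 ± 0.0182% of all counts in spleen and 0.546 ± 0.00701% in mLN.

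Neutrophil, erythroid and progenitor genes fell together. All 15 tested neutrophil genes fell (median log2 fold change -8.46, or -8.36 with genes at 0 to 3 counts set to their bound or ratio, camera adjusted p = 2.09e-14). S100a8, a calcium-binding protein gene of neutrophils (chromosome 3, 90668978 to 90670035), was at 146 ± 2.66 CPM in spleen and 0.421 ± 0.156 CPM in mLN (log2 fold change -8.41, SE 0.119, adjusted p = 4.24e-40). All 18 erythroid genes fell (median -6.78, adjusted p = 1.74e-17). Hbb-bs, a beta-globin gene that shares reads with Hbb-bt, had a log2 fold change of -6.66 and was at 6.96 ± 1.81 CPM in mLN. All 10 haem synthesis genes fell (median -1.54, adjusted p = 9.46e-07), with Alas2 at -6.19. The haematopoietic progenitor list fell in all 10 genes (median -3.46, adjusted p = 3.58e-07). Its granule protease gene Ctsg was at least 245.8-fold lower and Ms4a3 at least 78.86-fold lower. All 10 basophil, mast cell and eosinophil genes fell (median -5.25, or -4.68 with genes at 0 to 3 counts set to their bound or ratio, adjusted p = 3.18e-07). Ms4a2 was at least 58.32-fold lower, and Epx, with 1 count in mLN, had a ratio of 458 (81.83 to 18120). All 27 cell cycle genes fell beside these lists (median -1.08, adjusted p = 4.84e-13), among them the mitotic cyclin gene Ccnb1, from 33.9 ± 2.44 to 11.5 ± 1.89 CPM. The megakaryocyte and platelet list was not called by camera (3 lower and 1 higher of 5, adjusted p = 0.341), with Itgb3 at 0.88 and Ppbp at least 15.77-fold lower. It was called with no filter on low counts (adjusted p = 0.0016).

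Macrophage and dendritic-cell lists moved in both directions. The red-pulp macrophage list, of cells that clear old red cells, fell (11 lower and 0 higher of 16, or 12 and 1 adjusted over the list alone, median -0.76, adjusted p = 0.00146, but adjusted p = 0.0664 with an estimated correlation). The iron exporter gene Slc40a1 fell from 30.8 ± 2.50 to 2.89 ± 0.456 CPM, and Adgre1 and Vcam1 had log2 fold changes of -1.37 and -1.22. Spic, a transcription factor gene of these cells, had a log2 fold change of -0.71 (adjusted p = 0.027), whose call was lost without spleen replicate 1, mLN replicate 1 or mLN replicate 3 and with the effective-length offset. The iron and haem recycling list fell (10 lower and 1 higher of 13, median -0.43, adjusted p = 0.000634, but adjusted p = 0.107 with an estimated correlation). The marginal-zone and sinus macrophage list rose in 4 of 5 genes and fell in 1 (median 3.40, adjusted p = 0.018, but adjusted p = 0.107 with an estimated correlation). In it Cd209b had no counts in spleen and was at least 66.09-fold higher in mLN, while Cd209a had a log2 fold change of -1.20. These values, like those of Marco and Siglec1, are for cells that reached the sort. How fully such macrophages were recovered from each tissue was not measured. The monocyte list fell (10 lower and 2 higher of 13, or 11 and 2 adjusted over the list alone, median -0.92, adjusted p = 0.000351), with Ace at -1.92, Csf1r at -0.21 and Ly6c2 at 0.74. The type 1 dendritic-cell list fell (7 lower and 1 higher of 9, median -0.97, adjusted p = 0.004, but adjusted p = 0.0777 with an estimated correlation), with the chemokine receptor gene Xcr1 at -2.33 and the integrin gene Itgae at 1.70. The type 2 list fell (6 of 8 lower, median -0.98, adjusted p = 0.000947, but adjusted p = 0.0608 with an estimated correlation), with Itgax at -0.95. The migratory dendritic-cell list rose in 8 of 9 genes and fell in 1, Il4i1 (median 2.84, adjusted p = 2.90e-05). Aldh1a2, a gene of retinoic acid synthesis, rose from 0.549 ± 0.273 to 9.61 ± 1.75 CPM. The plasmacytoid list was not called by camera (5 lower and 3 higher of 9, or 6 and 3 adjusted over the list alone, adjusted p = 0.352). NK and cytotoxic genes fell (12 lower and 4 higher of 17, median -0.47, adjusted p = 0.0261, but adjusted p = 0.107 with an estimated correlation), with the egress receptor gene S1pr5 at -3.44, Ncr1 at -0.95 and Eomes at 0.67.

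**Figure D2:**
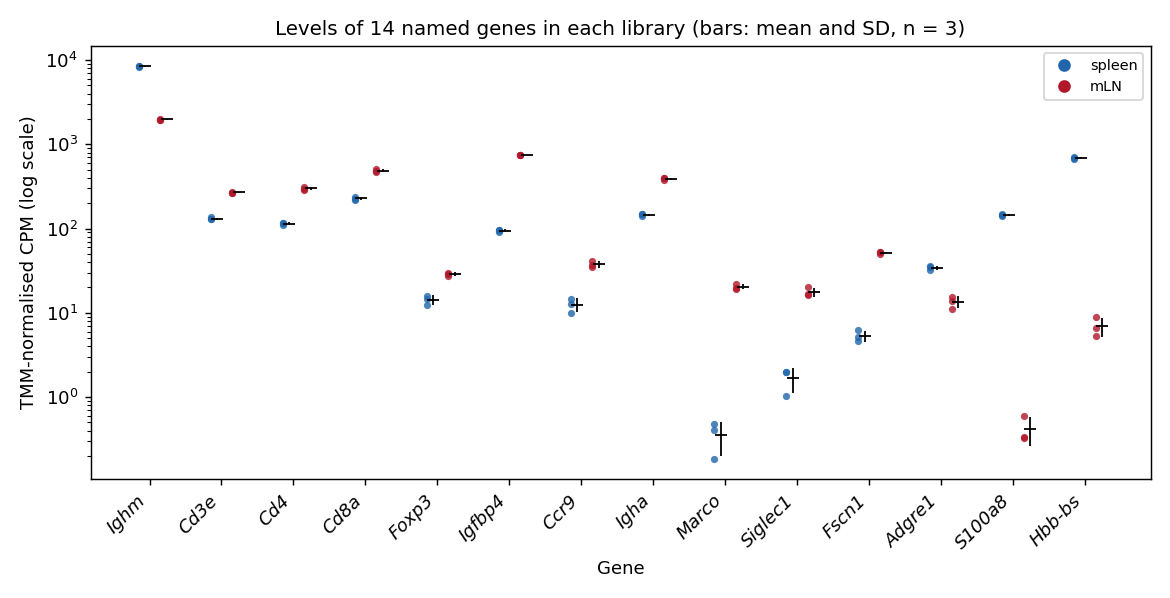
TMM-scaled CPM on a log axis of 14 named genes (horizontal axis) in each of 3 spleen and 3 mLN libraries, with a black mark for the mean and a bar for the SD of each tissue. Igfbp4 stood at 95.0 ± 3.01 CPM in spleen and 743 ± 4.92 CPM in mLN, and S100a8 at 146 ± 2.66 and 0.421 ± 0.156 CPM.

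Of 25 type I interferon response genes, 20 rose and 2 fell in mLN (median log2 fold change 0.73, camera adjusted p = 9.46e-07). Ifit1, an interferon-induced antiviral gene (chromosome 19, 34640871 to 34650009), rose from 6.58 ± 0.324 to 30.8 ± 4.33 CPM (log2 fold change 2.22, SE 0.124, adjusted p = 5.51e-19). Stat2 and Rsad2 had log2 fold changes of -0.16 and -0.72, and the call of Rsad2 was lost with the effective-length offset. The pan-T genes rose beside this list. The immediate-early and dissociation stress list rose in 13 of 18 genes and fell in 1 (median 0.38, adjusted p = 1.68e-05), with Fosb at 1.16, Hspa1a at 1.12 and Btg2 at -0.14. The gut homing and retinoic acid list rose in 5 of 8 genes and fell in 1 (median 0.73, adjusted p = 0.0111, but adjusted p = 0.106 with an estimated correlation). Ccr9, a receptor gene for homing to the small intestine, rose from 12.5 ± 2.33 to 37.7 ± 3.54 CPM, and Itga4 had a log2 fold change of -0.18. The glucocorticoid list was called at adjusted p = 0.0461 (6 higher and 3 lower of 10, median 0.23), but adjusted p = 0.134 with an estimated correlation. That call was lost on leaving out any library but mLN replicate 2 (adjusted p = 0.0537 to 0.0637), with a stricter filter (0.0522) and with the effective-length offset (0.127). The list for the unfolded-protein response and secretion fell (9 lower and 2 higher of 15, or 10 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.0275, but adjusted p = 0.111 with an estimated correlation). Without mLN replicate 2 its adjusted p was 0.0504. Xbp1 had a log2 fold change of -0.74 and Dnajc3 of 0.38.

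The remaining lists were not called by camera. In the antigen-receptor activity list 5 genes rose and 5 fell (adjusted p = 0.916), with Cd69 at 1.07 and Nr4a2 at -1.55. The inflammatory cytokine list had 3 higher and 5 lower of 11 (adjusted p = 0.295), with Il1b at -2.86. The complement and efferocytosis list had 2 higher and 4 lower of 12, or 3 and 4 adjusted over the list alone (adjusted p = 0.627), with Cd36 at -2.63 and Stab1 at 2.02, whose call was lost with the effective-length offset. The chemokine and egress receptor list had 8 higher and 6 lower of 18 (adjusted p = 0.428), with Cxcr2 at -5.32 and Ccr4 at 1.47. The integrin and adhesion list had 7 higher and 7 lower of 15 (adjusted p = 0.868), with Itgam at -1.64 and Itga6 at 1.07. The circadian clock list had 1 higher and 3 lower of 15 (adjusted p = 0.86), with Dbp at 0.61 and Bhlhe41 at -1.59. Glycolysis had 6 higher and 3 lower of 15 (adjusted p = 0.527), with Pfkp at 0.43 and Hk2 at -0.89. Lysosome genes had 4 higher and 8 lower of 15 (adjusted p = 0.294), with Npc2 at 0.66 and Grn at -0.97. Median, mean and test differed in sign for 6 of these lists. Complement had a median of 0.04 and a mean of -0.19 with the test downward, and circadian clock 0.01 and -0.10 with the test downward. The tests were upward for antigen-receptor activity (-0.04 and -0.01), chemokine receptors (0.19 and -0.22), integrins (0.04 and -0.08) and glycolysis (0.03 and -0.003015). Among markers of cells that a CD45 sort would remove, fibroblastic stroma (1 lower of 3, adjusted p = 0.596) and endothelial cells (2 lower of 4, adjusted p = 0.428) were not called. Their tested genes alone, 3 of 14 and 4 of 12 in the lists, summed to 5.96 and 6.39 CPM in spleen and 4.34 and 4.11 CPM in mLN. The adipocyte and the pancreas and intestinal epithelium lists had 2 and 1 tested genes and were not tested as lists. Over all their genes, tested or not, these 2 lists summed to 7.87 and 6.43 CPM in spleen and to 4.21 and 5.35 CPM in mLN.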

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

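The assumed coefficients of variation were chosen after seeing the data. Under the other alternatives the number of genes called stayed within 1.5 times of the reported one, from 4687 with the effective-length offset to 6587 with no filter, and no named gene changed direction. Of the 4687 calls with that offset, 4549 were shared with the reported calls, and 2 of the shared ones had the opposite direction. With library totals alone 6509 genes were called, 5983 of them shared with the reported calls, and 39.22% were higher in mLN against 47.79%. Leaving out a library gave 5854 to 6322 calls. With the replicate number as a block, 6455 genes and 29 lists were called, without the CD8 and glucocorticoid lists (both adjusted p = 0.0585). Deviations of same-numbered libraries correlated at 0.0267, 0.0275 and -0.0081, and numbers 1 and 2 but not 3 correlated best with their own number. These correlations are too weak to show that the numbers pair the libraries, and the labels do not say that they do. The assumed coefficients of variation went with a likelihood ratio test in place of the F-test, and what each of these changes contributed was not tested. At 0.2 this gave 2868 genes, 934 higher and 1934 lower, and at 0.4, 923, 197 higher and 726 lower, all of at least 2-fold. With an estimated correlation 14 lists were called, 5 higher and 9 lower. Some lists that lost their call had estimates above the preset 0.01, such as plasma cell (0.148). For others the estimate was lower, which argues against a larger correlation as the cause of their loss. These included CD4 (-0.0639, camera adjusted p from 0.00043 to 0.0553), CD8 (-0.212, from 0.0261 to 0.118) and NK (-0.0379, from 0.0261 to 0.107). Adjusted p also rose in lists that kept their call at negative estimates, by camera from 8.81e-18 to 0.0158 for pan-T (-0.0392). For neutrophil (-0.0271) it rose from 2.09e-14 to 0.0158. A call lost with this option is therefore by itself no measure of correlation between genes. What else caused the losses was not tested. Fry in its directional form, which does not compare a list with other genes, also called 8 lists that camera did not: follicular helper, type 2 lymphocyte, plasmacytoid, endothelial, inflammatory cytokine, complement, glycolysis and lysosome (adjusted p = 7.72e-06 to 0.0271). Lists that changed direction were called neither before nor after: type 2 lymphocyte (adjusted p = 0.606) and fibroblastic stroma (0.948) with no filter, megakaryocyte and platelet (0.844) with the stricter filter, and circadian clock without mLN replicate 1 (0.975, in a range of 0.727 to 0.991 over the libraries left out). The cause was not tested. Leaving out a library ended 3 to 5 calls of named genes, among Areg, Cp, Zbtb16, Atf4, Spic, Cdh5, Ccr2, Cox6a2 and Mfge8. Depth limits genes at 0 counts over a tissue, for which only a bound can be given.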

Other observations

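The tests on symbol families, on progenitor and erythroid genes and on interferon genes were chosen after the results were seen, and the contrasts between lists other than pan-T to pan-B were not fixed beforehand. Within the immunoglobulin heavy chain constant counts, Ighm made up 81.2 ± 0.233% in spleen and 53.5 ± 0.359% in mLN (SD, n = 3 each). Ighd made up 10.4 ± 0.128% and 20.7 ± 0.327%, Igha 1.41 ± 0.0604% and 10.6 ± 0.391%, and Ighg2b 1.32 ± 0.0697% and 6.16 ± 0.11%. These are shares: the level of Ighd itself, given here after its values were seen, fell from 1076 ± 5.84 to 770 ± 17 CPM (log2 fold change -0.48, adjusted p = 3.69e-20 by edgeR). Ighg2c went the other way, at 0.655 ± 0.0302% and 0.386 ± 0.0295%. Cytosolic ribosomal protein genes took 6.36 ± 0.0517% of all counts in spleen and 7.81 ± 0.0584% in mLN. Of these, 81 of 84 were called higher in mLN and 0 lower, and with library totals alone 81 were higher and 1 lower. Relative to pan-T genes, NK and cytotoxic genes were lower in mLN by a log2 difference of -1.69 (SE 0.0233) and regulatory T-cell genes by -0.51 (SE 0.0431). CD8 genes relative to CD4 genes differed by -0.51 (SE 0.0589), and class II genes relative to pan-B genes by 0.23 (SE 0.0141). Naive T-cell genes relative to pan-T genes differed by only 0.06 (SE 0.0327). Relative to pan-B genes, marginal-zone genes differed by -0.34 (SE 0.0478) and plasma-cell genes by -0.28 (SE 0.0708). Each of these had its 3 mLN libraries apart from its 3 spleen libraries (exact two-sided permutation p = 0.1, the smallest possible, and adjusted p = 0.1 over the 8 contrasts computed). They are differences of list means and not of cell shares, and members varied. In the regulatory list 8 genes rose, from Tnfrsf4 (0.32) to Gpr83 (1.735) with Foxp3 at 1.00, while Tigit (-0.82) and Ikzf2 (-0.38) fell. In the CD8 list Cd8a (1.10) and Cd8b1 (1.21) stood near Cd4 (1.39), but Runx3 was at 0.14 and Cd160 at -0.14.

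Genes that share a symbol stem were tested for enrichment among genes called at 2-fold or more, against all 14427 genes tested, in 640 hypergeometric tests with Benjamini-Hochberg adjustment, of which 3 passed. Upward these were the Cd stem with 16 of 81 genes (adjusted p = 2.02e-05), the Apol stem with 6 of 10 (adjusted p = 0.00014) and the Il stem with 8 of 42 (adjusted p = 0.0259). The same stems also held genes lower by 2-fold or more, 17 of 81 for Cd (adjusted p = 0.057), 4 of 10 for Apol (adjusted p = 0.3) and 6 of 42 for Il (adjusted p = 1), so none moved upward as a whole. The higher Apol genes were Apol7b, Apol7c, Apol7e, Apol9a, Apol9b and Apol10b, which may share reads with each other, so they cannot be taken as independent. The extent of sharing was not measured. The higher Il genes included Il7r, Il2ra, Il6ra and Il17rb. Several of the higher genes, such as Cd3e, Cd4, Cd8a, Apol7c, Il7r and Il2ra, belong to the fixed lists above. The stem results are therefore not independent of the list results. Histone genes of the Hist1h stem, lower in 8 of 22, missed the threshold (adjusted p = 0.0501). Xist had 0 to 3 counts in each library, and the Y-linked Ddx3y had 1884 to 2803.

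Erythroid and neutrophil genes were lower in mLN. Mature blood cells in the spleen as the only source are argued against by the progenitor list, which shares no gene with those lists. All 10 of its tested genes were lower, with a median log2 fold change of -3.46 with genes at 0 set to their bound, although Kit and Gata2 are also used by mast cells and basophils and Flt3 by dendritic cells. The CD45 sort would also remove mature red cells, which lack CD45, while a single aberrant spleen library is argued against by the summed CPM of the 3 lists, in the lowest spleen library 25.4 times that of the highest mLN library. Spleen CD45+ cells may include precursors of several lineages, a hypothesis that leaves open how much mature cells contribute.

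Interferon response genes were higher in mLN. The lowest median log2 fold change of the list over the scalings tried was 0.68. These scalings moved the median tested gene only by -0.0496 to 0.000525, so the list could hardly have reached 0. The choice among them does not account for the rise, and other scalings were not tested. A single aberrant mLN library is argued against, since 19 of 25 genes had all mLN libraries above all spleen libraries. A higher share of T cells alone cannot be told apart from a response of the cells. This test was first set against the pan-T median of 1.17, above which 5 genes lay by more than 2 SE. It was changed after that value was seen, because pan-T genes themselves ranged from 0.38 to 1.66. Above the highest of them only 1 gene, Ifit1, lay by more than 2 SE. Under the changed rule 5 or more such genes would have argued against a T-cell share alone, so 1 gene left the question undecided for the list. Both that share and a difference in interferon exposure between the tissues may contribute.

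The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 6569 genes, 1 of the 10 splits reached that count, and the highest of the others called 0 by edgeR. Each of the others put libraries of both tissues in each group, so the tissue difference widened the spread within groups. Their 0 calls are therefore no measure of calls made without a difference.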
